A study of Rattus norvegicus with 8 samples.

How the data were processed

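RNA-seq was measured in astrocytes of Sprague Dawley rat pups, in 8 libraries from 3 groups. In the control group (n = 2) the astrocytes met 12-273 BM melanoma cells, or their medium, that carried a scrambled hairpin. In the sh-APP group (n = 3) the melanoma cells carried a hairpin against the amyloid precursor protein gene. In the anti-Abeta group (n = 3) an antibody against amyloid beta was added to the scrambled-hairpin setting. The labels describe the exposure in differing ways. One names a co-culture, another names 24 h in medium from melanoma cells, and another describes astrocyte medium put on the melanoma cells. Which of these applied is not given in the sources used here. RNA was taken up with a column kit, and the library kit and its strandedness are not given in the sources used here.

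The deposited table holds raw counts per gene symbol, and the values were checked to be whole numbers whose totals differ between libraries. The authors' notes name FastQC 0.11.7, Trimmomatic 0.36, STAR 2.6.0a, SAMtools 1.9, HTSeq 0.11.1, DESeq2 1.24.0 and the rat build rn6, without saying what each was set to do. The table has 28546 gene entries, of which 8853 hold no count in any library. Of the gene symbols, 26 had been turned into dates, and 23 of these passed the filter. The 4 that share a date with another were kept apart by their place in the table, and none of the dates is named in the text. The total count per library ran from 34250464 to 47831595, and the tested genes held nearly all of it. Intervals from counting are narrow at this depth, so the spread between libraries sets the precision.

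All 8 libraries entered a single fit in edgeR 4.0.16 (R 4.3.3), with group as the only term and 5 residual degrees of freedom. Genes were kept by filterByExpr with its minimum count of 10 and minimum total of 15, which left 14445. Library totals were scaled by TMM factors. Each contrast was tested with edgeR's quasi-likelihood test in its robust form, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. The 4 contrasts were sh-APP against control, anti-Abeta against control, sh-APP against anti-Abeta, and the mean of both arms against control. Fold changes are on the log2 scale, and their standard errors (SE) are the fold change divided by the square root of the F statistic. Levels are CPM (counts scaled to the same total in each library) after TMM scaling, as mean ± SD. The labels do not say whether libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries. A rat gene table of a later assembly than rn6 was used to look for genes that overlap on the chromosome. It matched 12988 of the tested symbols (89.9%) and 172 of the 179 named genes, and 52 of these overlap another gene. Reads from overlapping genes cannot be assigned by strand here, so the levels of such genes are less certain. The text marks the overlap for only part of these genes, so a gene without a mark may overlap another too.

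Contrasts, tests, gene lists, the rule for named genes and all alternatives except 2 were chosen before the data were examined. The 28 lists comprise 20 pathway lists and 8 lists of cell type markers, and hold 711 different genes, tested or not. They were tested with camera of limma 3.58.1 at its preset correlation of 0.01, on log2 CPM with a prior count of 2, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. The rule takes, for each arm, the 8 genes with the largest fold change in each direction among called genes that do not overlap between the groups and reach a mean of 5 CPM. It also takes up to 4 called members of each list with the smallest p, and a fixed set (App, Gfap, Vim, Lcn2, C3, Serpina3n, Il6, Ccl2, Cxcl10, Apoe and Clu). For sh-APP against anti-Abeta the rule takes 5 genes in each direction, and for the mean of both arms the 10 genes called the same way in both arms with the smallest larger p. The text prints part of these. Other members of small counts were picked after their values were seen, and the text marks them. Il6 had 8 counts in all libraries together and was not tested, and Serpina3n is not analysed here.

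The alternatives were DESeq2 1.42.0, limma-voom, size factors of DESeq2's kind, upper-quartile factors, no low-count filter, a filter of 1 CPM in 3 libraries, the non-robust spread, fits of only the groups compared, the replicate number as a block, and leaving out each library in turn. The 2 added after the data were seen were library totals with no composition factor and a fit without the 13 mitochondrially encoded genes with a gene name. Single values per library were compared with exact permutation tests in SciPy 1.17.1. The tests were checked on simulated data with 200 changed genes: edgeR recovered 47.8% of genes changed 1.5-fold, 79.1% at 2-fold and 93.9% at 4-fold for sh-APP against control, with 10 false calls. The bias of GC content or gene length was not tested, since no annotation of the rn6 build was used here.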

Results

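The 8 libraries covered astrocytes exposed to melanoma cells with a scrambled hairpin (control, n = 2), with a hairpin against the amyloid precursor gene (sh-APP, n = 3), or with the scrambled hairpin and an antibody against amyloid beta (anti-Abeta, n = 3). The total count was 39951265 and 40113512 in the control libraries. It was 41304519, 44743406 and 41707471 in sh-APP replicates 1 to 3, and 34250464, 41403721 and 47831595 in anti-Abeta replicates 1 to 3. The first principal component (43.4% of the variance) placed the control libraries lowest, anti-Abeta between, and sh-APP highest, and the second (12.3%) set anti-Abeta replicate 1 apart (-47.4). Anti-Abeta replicate 2 differed most from its group: chi-square per degree of freedom against counting noise was 44.3 and 30.1 for its pairs and 16.6 to 19.8 for the other pairs within groups. Library numbers are 1 to 2 in control, 4 to 6 in anti-Abeta and 7 to 9 in sh-APP. The hairpin and the antibody are the 2 means the study uses against amyloid beta.

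App, the rat gene for the amyloid precursor protein, was checked first. It had 573 ± 19.8 CPM in control (mean ± SD, n = 2), 612 ± 31.7 in sh-APP (n = 3) and 539 ± 32.3 in anti-Abeta (n = 3). Its log2 fold change was 0.09 ± 0.08 (SE) in sh-APP (adjusted p = 0.323, edgeR) and -0.09 ± 0.08 in anti-Abeta (adjusted p = 0.414). The hairpin was in the melanoma cells, so the astrocytes' own App does not measure the knockdown, and amyloid beta itself was not measured by these libraries.

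The first comparison asks what a hairpin against the amyloid precursor gene in the melanoma cells changes in the astrocytes. Across all 14445 tested genes 53.7% were called (3723 higher and 4027 lower), so a count of called list members does not by itself set a list apart. Of 18 astrocyte markers 12 were called higher, of 16 complement genes 7, and of 39 proliferation genes 34 were called lower. These 3 lists passed at camera's preset correlation, with adjusted p = 0.609 with an estimated correlation. Gfap, the intermediate filament protein of astrocytes, rose from 2911 ± 19.4 CPM in control (SD, n = 2) to 6532 ± 893 in sh-APP (n = 3), a log2 fold change of 1.17 ± 0.11 (SE). C3, the central component of complement, rose by 1.49 ± 0.13, from 42.2 ± 8.39 to 119 ± 16.8 CPM. Hspb1, a small heat shock protein, rose by 2.20 ± 0.19, and Clu, the secreted chaperone clusterin, by 1.15 ± 0.08. Ccl2, the chemokine that draws monocytes, fell from 1231 ± 17.8 to 659 ± 75.4 CPM (log2 fold change -0.90 ± 0.10). For each of these genes, all 3 sh-APP libraries lay on the same side of both control libraries. Clu overlaps another gene on the chromosome.

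**Figure D1:**
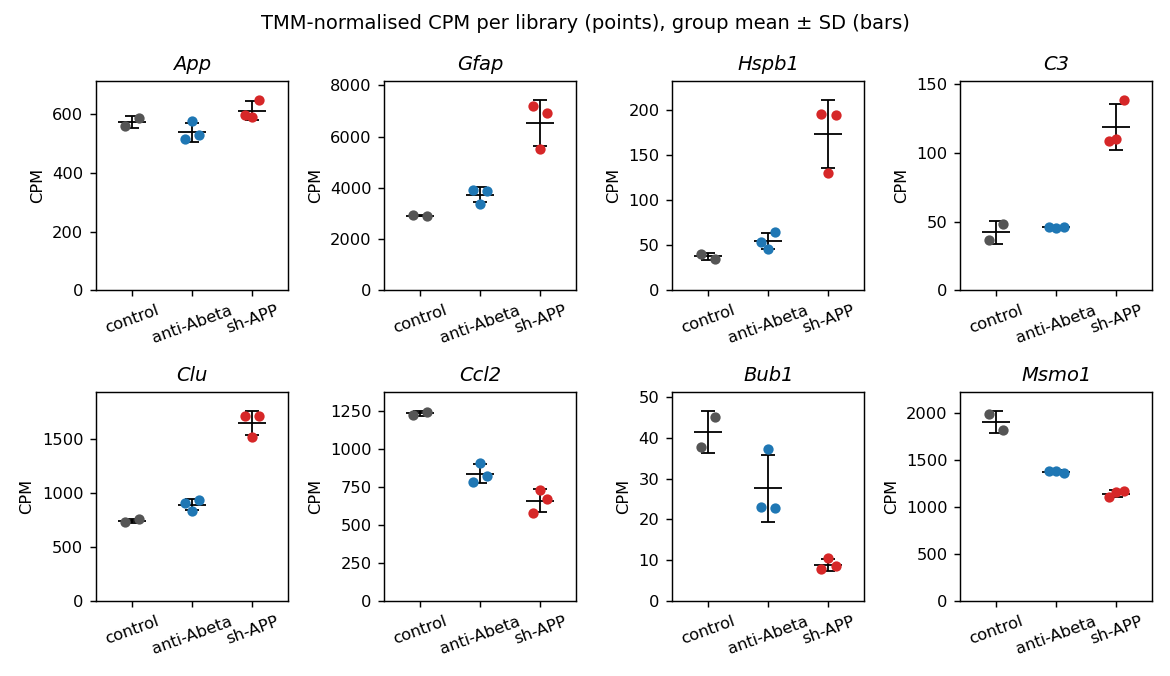
CPM after TMM scaling (vertical axes, from 0) of 8 genes in each library (points), with the group mean and SD (bars), for control (n = 2), anti-Abeta (n = 3) and sh-APP (n = 3). Gfap averages 2911 CPM in control and 6532 in sh-APP, and Bub1 averages 41.4 and 8.93.

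Of the 18 tested astrocyte markers, 12 rose and 1 fell in sh-APP against control. Aldoc, an aldolase of astrocytes, rose by 0.90 ± 0.09 on the log2 scale (SE), Ntsr2, a neurotensin receptor, by 1.16 ± 0.15, and Fgfr3, a growth factor receptor, by 0.69 ± 0.07. The 1 that fell was the gap junction gene Gja1 (-0.78 ± 0.11), picked after its values were seen. The list passed its test (median 0.42, camera adjusted p = 0.0172), with adjusted p = 0.609 with an estimated correlation. Of 12 pan-reactive astrocyte genes, 7 rose and 3 fell, the latter being Cxcl10 together with Osmr and Cp, which were picked after their values were seen. Aspg, an asparaginase, rose by 2.46 ± 0.26 and Lcn2, a secreted lipocalin, by 0.73 ± 0.09. Of 11 genes of the A1 reactive list, 6 rose and 2 fell (Gbp2 and Amigo2, picked after their values were seen), and of 11 of the A2 list, 4 rose and 4 fell, with Tm4sf1 at -1.84 and Ptx3 at 0.61. Adjusted over the list alone, the A1 counts were 7 and 2, and the A2 counts 4 and 5. These 3 lists did not pass (adjusted p = 0.280, 0.173 and 0.893). Vim, another intermediate filament gene, rose by 0.29 ± 0.08, a call lost without control replicate 1 (adjusted p = 0.124).

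Of 16 tested complement genes, 7 rose and 0 fell in edgeR's test (8 and 1 at an unadjusted p under 0.05, and 7 and 0 with DESeq2 and with limma-voom). C1s and C1r, the proteases of the first complement complex, rose by 0.90 ± 0.11 and 0.96 ± 0.12, and Serping1, which inhibits them, by 0.67 ± 0.08; C1r overlaps another gene. The list passed (median 0.82, adjusted p = 0.0417; adjusted p = 0.609 with an estimated correlation), but not without sh-APP replicate 3 (0.0505), anti-Abeta replicate 1 (0.0506) or anti-Abeta replicate 2 (0.0655), over a leave-one-out range of 0.0152 to 0.0655. With library totals alone its adjusted p was 0.0899. Among NF-kB targets, 14 of 26 rose and 2 fell (Nfkbiz and Vcam1, picked after their values were seen), and the list passed (median 0.38, adjusted p = 0.0202; adjusted p = 0.609 with an estimated correlation). Relb, a subunit of NF-kB, rose by 0.68 ± 0.09. Bcl3, Nfkbib and Nfkbie, which belong to the family of inhibitors of NF-kB, rose by 0.69 ± 0.10, 0.67 ± 0.10 and 0.55 ± 0.09. Of 28 cytokines and chemokines, 4 rose and 4 fell, and the list did not pass (adjusted p = 0.764). Cxcl1, a chemokine for neutrophils, had a log2 fold change of -0.96 ± 0.18, and Cxcl14 rose by 0.49 ± 0.08. Cxcl6 was at -1.77, a call lost without control replicate 2 (adjusted p = 0.0554). Cxcl10 changed by -1.37, a call lost without control replicate 2 (adjusted p = 0.224), without sh-APP replicate 2 (0.0612), with DESeq2 (0.0520) and with library totals alone (0.0860), and it overlaps Art3.

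Of 35 genes of the type I interferon response, 4 rose and 9 fell (4 and 8 adjusted over the list alone), and the list did not pass (adjusted p = 0.520). Ifi44 had a log2 fold change of -1.10 while Eif2ak2, a kinase that senses double-stranded RNA, went from 101 ± 4.60 to 50.6 ± 7.44 CPM and Stat2 rose by 0.65 ± 0.10. Of 20 antigen presentation genes, 8 rose and 2 fell. The class I gene RT1-A1 and Tapbp, which loads peptides, rose by 0.74 ± 0.09 and 0.81 ± 0.12. The 2 that fell were B2m, the light chain of class I molecules (-0.94 ± 0.08), and Erap1, which trims peptides (-0.77 ± 0.08). RT1 genes resemble each other closely, so reads may have been shared among them. The list passed (median 0.41, adjusted p = 0.0417), but not without control replicate 1 (0.163, in a leave-one-out range of 0.00676 to 0.163) or with library totals alone (0.0527), and its adjusted p was 0.609 with an estimated correlation.

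Of 39 tested proliferation genes, 0 rose and 34 fell in sh-APP against control in edgeR's test (1 and 35 at an unadjusted p under 0.05, and 0 and 34 with DESeq2 and with limma-voom). Bub1, a kinase of the mitotic checkpoint, went from 41.4 ± 5.23 to 8.93 ± 1.45 CPM (log2 fold change -2.21 ± 0.21). Ccna2, cyclin A2, had a fold change of -2.09 ± 0.22, Prc1 of the mitotic spindle -1.53 ± 0.16, and Tyms, which makes thymidylate, -1.55 ± 0.14. Among the largest falls by the naming rule were Sgo2, Cenpk, Ncapg, Cep55, Esco2, Ect2 and Kif20b, with log2 fold changes from -2.56 to -2.43. These genes are known for chromosome segregation, cohesion or cytokinesis. The list passed (median -1.21, adjusted p = 2.52e-08), with adjusted p = 0.609 with an estimated correlation. Sgo2, Cenpk, Ncapg, Ect2, Kif20b and Prc1 overlap other genes.

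Of 49 extracellular matrix genes, 22 rose and 6 fell (23 and 6 adjusted over the list alone). Ncan and Bcan, proteoglycans of the brain matrix, rose by 1.18 ± 0.12 and 0.94 ± 0.11, Lamb2, a laminin chain, by 0.88 ± 0.08, and Sparc, a secreted matrix protein, by 0.71 ± 0.07. The list passed (median 0.37, adjusted p = 0.0202; adjusted p = 0.609 with an estimated correlation). Of 29 immediate early genes, 13 rose and 4 fell (15 and 5 adjusted over the list alone). Junb and Jund, of the AP-1 family, rose by 0.87 ± 0.09 and 0.85 ± 0.12, and Dusp6, a phosphatase of ERK kinases, had a log2 fold change of -0.71 ± 0.09. The other 3 that fell were Egr3, Ier5 and Klf4, picked after their values were seen. The list passed (median 0.55, adjusted p = 0.0420), but not without control replicate 2 (0.156), sh-APP replicate 1 (0.0624) or anti-Abeta replicate 1 (0.0506), in a leave-one-out range of 0.0159 to 0.156, or with library totals alone (0.0527). Its adjusted p was 0.636 with an estimated correlation.

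Of 28 genes of amyloid precursor processing and clearance, 16 rose and 5 fell, and the list did not pass (adjusted p = 0.0652). Apoe, the lipid carrier, rose by 0.71 ± 0.10 and Scarb1, a lipoprotein receptor, by 0.57 ± 0.08. The 5 that fell were Picalm, which acts in endocytosis (-1.06), and Adam10, Adam17, Ide and Abca1, which were picked after their values were seen. Of 21 TGF-beta and YAP targets, 7 rose and 4 fell (adjusted p = 0.415). Tagln, an actin-binding protein, rose by 1.99 ± 0.11, and Tgfb2 had -1.34. The largest rises by the naming rule were Stmn2 (2.53), Aspg, Hspb1, Entpd2 (2.18), Tagln, Etnk2 (1.94), Ppp1r1b (1.93) and Cyp1a1 (1.87). In all, 7750 of 14445 genes changed (3723 higher and 4027 lower) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, of which 291 rose and 1329 fell by more than 2-fold. TMM factors were 0.90 and 0.92 in the control libraries and 1.04 to 1.06 in sh-APP, and with library totals alone 5174 rose and 3091 fell, so the balance of rises and falls rests on the scaling.

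**Figure D2:**
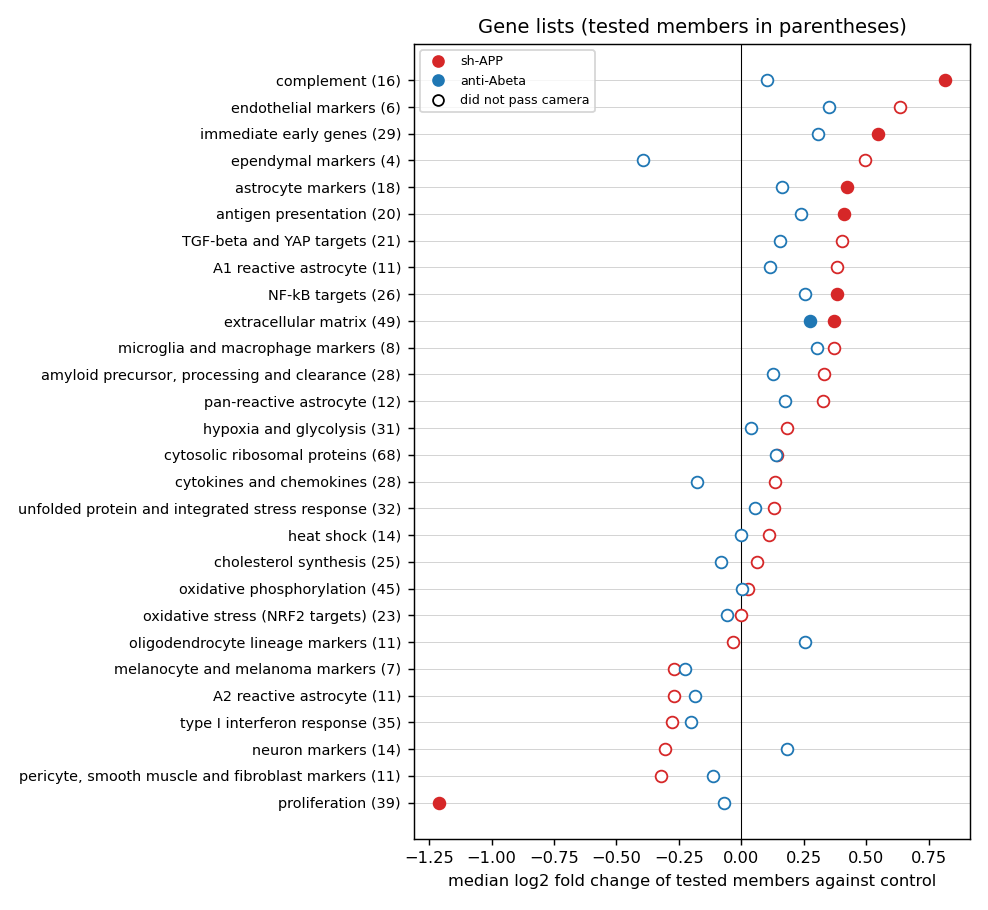
Median log2 fold change against control (horizontal axis) of the tested members of each of the 28 gene lists, in sh-APP (red) and anti-Abeta (blue). Filled points pass camera at its preset correlation, which 7 lists do in sh-APP and 1 does in anti-Abeta.

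Markers of other cell types moved in both directions in sh-APP against control. Of 11 oligodendrocyte lineage markers, 1 rose (Olig1, 0.32) and 2 fell (Pdgfra, from 33.7 ± 1.71 to 16.9 ± 0.374 CPM, and Ugt8, at -2.37). Of 14 neuron markers, 4 rose and 4 fell (4 and 5 adjusted over the list alone), among them Snap25 (-1.57), Map2 (-1.24), Elavl4 (-0.68) and Stmn2. Of the 8 microglia and macrophage markers only Tyrobp was called, at a mean of 0.0830 CPM in control and 0.609 in sh-APP, a call lost without control replicate 2 (adjusted p = 0.0838). Of 6 endothelial markers, Kdr and Egfl7 rose (1 of 6 adjusted over the list alone), Kdr at means of 0.0417 and 0.348 CPM and with its call lost without control replicate 2 (0.226) and sh-APP replicates 1 (0.0676) and 2 (0.0809). Among 11 pericyte, smooth muscle and fibroblast markers 3 rose and 2 fell, among 4 ependymal markers 2 rose and 1 fell (1 and 0 with limma-voom), and among 7 melanocyte and melanoma markers 1 rose and 3 fell. The ependymal calls of Rsph1 and Tekt1 were lost without control replicate 1 (0.106 and 0.247) or 2 (0.0770 and 0.0866) and sh-APP replicate 1 (0.0534 and 0.103) or 3 (0.0767 and 0.122), and that of Dnah12 without control replicate 2 (0.613) and sh-APP replicate 3 (0.0927). Gpnmb, a glycoprotein of the melanocyte list, went from 4218 ± 48.2 to 2248 ± 102 CPM. Slc24a5, which overlaps Myef2, stood at 121 and 109 CPM in control and at 29.5 to 42.5 in sh-APP. Mitf stood at 43.3 and 39.7 against 25.4 to 29.0, while S100a1 rose from 33.0 and 34.8 to between 50.7 and 51.7. One label names a co-culture, and whether RNA of melanoma cells entered the libraries was not tested. None of these 7 lists passed, with adjusted p from 0.547 to 0.991. Median, mean and test differed in sign for the neuron, pericyte, NRF2, cholesterol and oxidative phosphorylation lists.

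The next comparison asks what an antibody against amyloid beta changes. Across all 14445 tested genes 29.2% were called (1832 higher and 2391 lower). Of 49 extracellular matrix genes 16 rose and 1 fell, in a list that passed (adjusted p = 0.0146; adjusted p = 0.726 with an estimated correlation). Genes of cholesterol synthesis and NRF2 targets moved both ways, and these lists did not pass. Msmo1, which removes methyl groups from sterols, went from 1908 ± 119 CPM in control (SD, n = 2) to 1378 ± 16.6 in anti-Abeta (n = 3), a log2 fold change of -0.47 ± 0.07 (SE). Sc5d had -0.47 ± 0.07, Nsdhl -0.47 ± 0.08 and Sqle -0.40 ± 0.07, all in the same pathway, of which 7 other genes rose. Prdx1, a peroxiredoxin, had -0.60 ± 0.09, Me1, which makes NADPH, -0.46 ± 0.07, and Gsta1, a glutathione transferase, -0.54 ± 0.09. Ccl2 went from 1231 ± 17.8 to 836 ± 62.6 CPM (-0.56 ± 0.10), and Relb rose by 0.54 ± 0.09. For each gene named in this paragraph all 3 anti-Abeta libraries lay on the same side of both control libraries, and the calls held with each library left out in turn. These genes are only part of the named ones and do not stand for the arm. Most of its named calls were lost with a control library left out, as given below.

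The counts of extracellular matrix genes in anti-Abeta were 19 higher and 1 lower adjusted over the list alone. Col6a2, a chain of collagen VI, rose by 0.55 ± 0.10. Lamb2 rose by 0.48 ± 0.08 and Bcan by 0.52 ± 0.11, calls lost without control replicate 1 (adjusted p = 0.0578 and 0.0529), and for Bcan also without control replicate 2 (0.0574). The 1 that fell was Col11a1, picked after its values were seen. This was the only 1 of the 28 lists that passed at the preset correlation (median 0.28). Of 25 cholesterol synthesis genes, 7 rose and 10 fell (8 and 10 adjusted over the list alone), and the list did not pass (adjusted p = 0.704). Mvk, picked after its values were seen, rose by 0.37 ± 0.09. Of 23 NRF2 targets, 3 rose (Tkt, Osgin1 and Abcc1, picked after their values were seen) and 6 fell, with adjusted p = 0.694 for the list. Of 26 NF-kB targets, 8 rose and 2 fell (adjusted p = 0.136), and of 20 antigen presentation genes, 4 rose and 2 fell (adjusted p = 0.158), with Erap1 at -0.40. Of 29 immediate early genes, 9 rose and 0 fell in edgeR's test (11 and 3 at an unadjusted p under 0.05, 9 and 2 with DESeq2, 6 and 0 with limma-voom, 10 and 1 adjusted over the list alone; adjusted p = 0.136 for the list). Junb at 0.42 lost its call without control replicate 1 (adjusted p = 0.0747).

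In anti-Abeta, of 12 pan-reactive astrocyte genes, 2 rose (Gfap and Hspb1) and 2 fell (Cp and Osmr), or 6 and 3 adjusted over the list alone, and the list did not pass (adjusted p = 0.704). Without control replicate 1 the calls of Hspb1 (adjusted p = 0.132), Cp (0.0666) and Osmr (0.144) were lost, and those of Hspb1 and Osmr also without control replicate 2 (0.218 and 0.186), anti-Abeta replicate 1 (0.0672 and 0.116) and anti-Abeta replicate 3 (0.122 and 0.105), and that of Osmr without sh-APP replicate 2 (0.0536) and with library totals alone (log2 fold change -0.11, adjusted p = 0.361, against -0.26). Gfap rose by 0.36 ± 0.11, a call lost without control replicate 1 (adjusted p = 0.165) or 2 (0.129) and without anti-Abeta replicate 1 (0.0847) or 3 (0.0872). Lcn2 had a log2 fold change of 0.24 ± 0.09 (adjusted p = 0.0623), Vim of 0.23 ± 0.08 (0.0538), Cxcl10 of -0.30 ± 0.42 (0.631) and C3 of 0.11 ± 0.13 (0.545), none of which passed. Of 16 complement genes, 0 rose and 0 fell in edgeR's test, at an unadjusted p under 0.05, and with DESeq2 and limma-voom. Of 11 A1 genes 0 were called in edgeR's test (1 rise and 1 fall at an unadjusted p under 0.05, and 0 with DESeq2 and limma-voom), and of 11 A2 genes 2 fell (1 adjusted over the list alone, and 4 with DESeq2, with limma-voom and at an unadjusted p under 0.05), with Cd109, a surface glycoprotein, at -0.77. Apoe rose by 0.49 ± 0.10, a call lost without control replicate 1 (adjusted p = 0.0705), and Clu by 0.26 ± 0.08, a call lost without control replicate 1 (0.204) or 2 (0.0872) and without anti-Abeta replicate 1 (0.0783) or 3 (0.0978). Of 18 astrocyte markers, 5 rose and 3 fell. Aqp4, the water channel, was at -0.43 and lost its call without control replicate 1 (0.0629) or 2 (0.0546). Of 39 proliferation genes, 2 rose (Mcm2 and Mcm7) and 3 fell (Tyms, Pcna and Bub1, the last picked after its values were seen). With DESeq2 2 rose and 5 fell, with limma-voom 2 and 6, and at an unadjusted p under 0.05 2 and 7. The calls of Tyms, Pcna, Mcm2 and Mcm7 were lost without control replicate 1 (adjusted p = 0.0522, 0.118, 0.248 and 0.243), that of Mcm2 without anti-Abeta replicate 1 (0.0544), and those of Mcm2 and Mcm7 without anti-Abeta replicate 3 (0.0620 and 0.0542). With library totals alone that of Pcna was lost (0.0551). The list had a median of -0.07 and did not pass (adjusted p = 0.694; -0.24 and 0.210 without anti-Abeta replicate 2). Bub1 stood at 37.1 CPM in that replicate and at 22.9 and 22.8 in the other 2, against 41.4 in control.

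Other lists did not pass in anti-Abeta. Of 28 cytokines and chemokines, 1 rose and 4 fell, of 35 interferon genes 1 rose and 5 fell, of 21 TGF-beta and YAP targets 1 rose and 1 fell, and of 28 amyloid processing genes 9 rose and 5 fell. Of 11 oligodendrocyte lineage markers 3 rose and 1 fell, and of 14 neuron markers 0 rose and 3 fell (2 and 3 at an unadjusted p under 0.05, 1 and 2 with DESeq2, 0 and 3 with limma-voom). Of 7 melanocyte markers 2 fell, of 4 ependymal markers 1 fell, and of 11 pericyte markers 1 rose (Tagln, 0.56). Among microglia and endothelial markers 0 were called in edgeR's test, DESeq2 or limma-voom (1 and 0 at an unadjusted p under 0.05). Among the larger changes by the naming rule, calls that held with each library left out include Ier5l (0.79), Mlf1 (-1.21) and Iqcb1 (-1.09). In all, 4223 genes changed (1832 higher and 2391 lower), 28 of them up and 83 down by more than 2-fold. The balance turned with library totals alone (3590 higher and 1417 lower) and with upper-quartile factors (2391 and 2047). The count fell to 439 (54 higher and 385 lower) without control replicate 1, to 2431 without control replicate 2 and to 2594 without anti-Abeta replicate 3. Of 97 named genes called here, 76 lost the call without control replicate 1, against 7 of 113 in sh-APP. Median, mean and test differed in sign for the A1, amyloid, oxidative phosphorylation, neuron and pericyte lists.

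Direct comparison of the arms asks which changes differ between hairpin and antibody; control libraries enter it only through the filter, scaling and spread of the shared fit. Across all 14445 tested genes 26.1% were called (1452 higher and 2316 lower in sh-APP). The lists with the smallest p were proliferation, astrocyte markers and complement. The difference was 0.81 ± 0.10 on the log2 scale for Gfap, 1.38 ± 0.11 for C3 and 0.89 ± 0.07 for Clu, each higher in all 3 sh-APP libraries than in all 3 anti-Abeta libraries. Of 39 proliferation genes, 0 were higher and 38 lower in sh-APP by edgeR, by DESeq2, by limma-voom and at an unadjusted p under 0.05 (list median -1.12, adjusted p = 1.02e-17). Of 18 astrocyte markers, 10 were higher and 1 lower (median 0.30, adjusted p = 4.29e-05; 13 and 1 adjusted over the list alone). Of 16 complement genes, 8 were higher and 1 lower (median 0.57, adjusted p = 0.000629; 10 and 1 adjusted over the list alone). The adjusted p of these 3 lists was 0.297 with an estimated correlation. By the naming rule, Stmn2 (2.37), Cyp1a1 (2.11), Aspg (1.81), Serpinf1 (1.80) and Entpd2 (1.74) were the most raised in sh-APP. Sgo2 (-2.53), Ect2 (-2.08), Cep55 (-1.96) and Depdc1 (-1.96) were among the most lowered.

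In the direct comparison 9 more lists passed. These were amyloid processing (10 higher and 3 lower of 28, adjusted p = 0.00841), pan-reactive (5 and 0 of 12, 0.0218), the unfolded protein and integrated stress response (10 and 3 of 32, 0.0218), A1 (4 and 1 of 11, 0.0234), NF-kB (5 and 1 of 26, 0.0234), NRF2 targets (9 and 1 of 23, 0.0234), ependymal (2 and 0 of 4, 0.0392) and immediate early genes (6 and 1 of 29, 0.0408), with oligodendrocyte lineage markers lower (0 and 3 of 11, 0.0218). A1 lost its call without anti-Abeta replicate 1 (0.0749), and immediate early genes without sh-APP replicate 1 (0.0924) or anti-Abeta replicate 2 (0.105), and ependymal markers with library totals alone (0.0572). None passed with an estimated correlation, where adjusted p ran from 0.297 to 0.502. In all, 3768 genes differed (1452 higher and 2316 lower in sh-APP), and 2233 without sh-APP replicate 1. With library totals alone 1923 were higher and 1961 lower, so the excess of lower genes rests on the scaling. Median, mean and test differed in sign for the interferon, endothelial and pericyte lists.

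Taking both arms as intended to lower amyloid beta, 7069 genes changed in their mean against control (3341 higher and 3728 lower), and 4490 without control replicate 1. The balance turned with library totals alone (4872 higher and 2721 lower) and with upper-quartile factors (3954 and 3315). Both arms called 4058 genes the same way, 1739 higher and 2319 lower, and 2 in opposite ways, where independent lists would share 1139. With library totals alone 3427 shared genes were higher and 1362 lower, and with upper-quartile factors 2289 and 1969, so this balance too rests on the scaling. The fold changes correlated across genes (Pearson r = 0.738), which are not independent replicates. The arms share both control libraries, and in 20 simulations of unchanged groups against the same controls r averaged 0.620 and at most 1 gene was shared. The simulations drew each gene independently, so their range may be too narrow. With a control library of its own for each arm, a test chosen after the data were seen, r was 0.297 or 0.336 (at most 0.0868 in simulations). These fits cover 14930 genes instead of 14445 and have 1 control library per arm. Their r is therefore not directly comparable with 0.738. The covariance was 0.259 or 0.281, against 0.319 with the shared controls. Of the shared genes, 94.8% changed more in sh-APP, and the median ratio of the anti-Abeta to the sh-APP fold change was 0.603. Without control replicate 1 the shared genes were 435, without control replicate 2 they were 2368, and without anti-Abeta replicate 3 they were 2518.

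**Figure D3:**
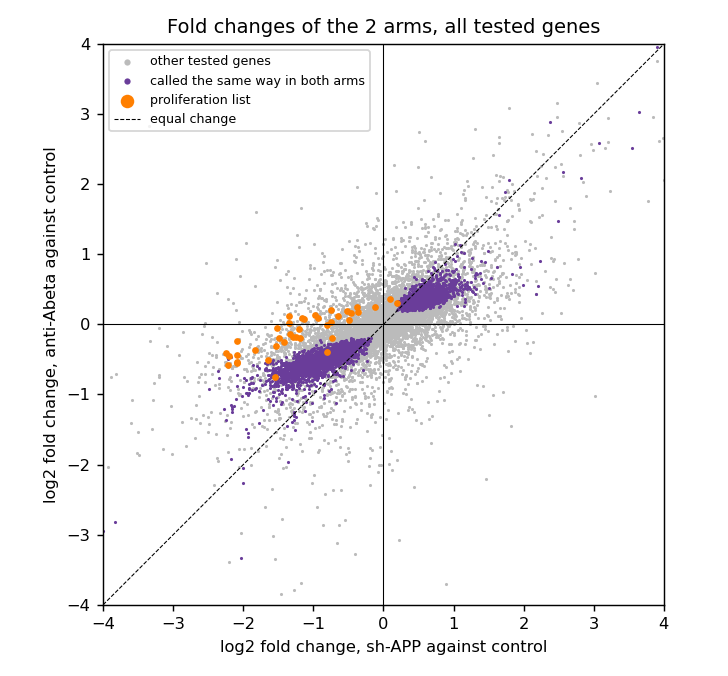
Log2 fold change against control of every tested gene in sh-APP (horizontal) and anti-Abeta (vertical), with genes called the same way in both arms in purple, proliferation genes in orange and equal change as a dashed line. The correlation is 0.738, and 40 genes lie outside the axes.

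The genes shared with the smallest p all fell in both arms. Eif2s2, a subunit of a translation initiation factor, averaged 205 CPM in control, 111 in sh-APP and 137 in anti-Abeta, a mean log2 fold change of -0.73 ± 0.06 (SE). Cox20, an assembly factor of cytochrome c oxidase, had -1.12 ± 0.09, and Tiprl, a regulator of protein phosphatases, -1.07 ± 0.08. Tapt1, Ints6, Utp11, Chpt1, Rmdn1 and Lactb2 had -0.89, -0.90, -0.85, -0.83, -0.88 and -0.97, and the other gene of this set is a mitochondrial transcript without a gene name. Ints6, Chpt1, Rmdn1 and Lactb2 overlap other genes. Of the 28 lists, 6 passed for the mean of both arms: proliferation (median -0.64, adjusted p = 7.4e-05), extracellular matrix (0.38, 0.00912), NF-kB targets (0.33, 0.0413), and antigen presentation, immediate early genes and astrocyte markers (0.0497 each). A list can pass here on the change of 1 arm: the proliferation median was -1.21 in sh-APP and -0.07 in anti-Abeta. At the preset correlation all 6 passed in sh-APP, and only extracellular matrix passed in anti-Abeta. With an estimated correlation the adjusted p of all 6 was 0.765. Of these only proliferation and extracellular matrix kept the call with each library left out in turn. NF-kB lost the call without control replicate 1 (0.0744) or anti-Abeta replicate 2 (0.0633). Antigen presentation lost it without control replicate 1 (0.405), the sh-APP replicates 1 to 3 (0.0613, 0.0607 and 0.0546) or the anti-Abeta replicates 1 to 3 (0.0565, 0.0633 and 0.0651). Astrocyte markers lost it without control replicate 1 (0.105), sh-APP replicates 1 and 3 (0.0613 and 0.0715) or the anti-Abeta replicates 1 to 3 (0.0565, 0.0743 and 0.0651), and immediate early genes without control replicate 2 (0.230), sh-APP replicates 1 and 3 (0.0651 and 0.0546) or anti-Abeta replicates 1 and 3 (0.0684 and 0.0651). Antigen presentation and immediate early genes also lost it with library totals alone (0.0762 and 0.0675). Median, mean and test differed in sign for the NRF2, heat shock, neuron, ependymal, melanocyte and oxidative phosphorylation lists.

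Transcripts encoded in mitochondria were lower in both arms. The 13 genes with a gene name held 5.63 ± 0.828% of counts in control (SD, n = 2), 2.28 ± 0.280% in sh-APP (n = 3) and 3.32 ± 0.310% in anti-Abeta (n = 3). Mitochondrial transcripts without a gene name are outside this share. All 13 were called lower in both arms, with median log2 fold changes of -1.53 and -0.86. By a two-sided exact permutation test of the share p was 0.2 for each arm against control, 0.1 between the arms and 0.0714 for both arms together against control, each the smallest that the number of libraries allows. The median of the 45 tested nuclear genes of oxidative phosphorylation was 0.03 in sh-APP and 0.00 in anti-Abeta.

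**Figure D4:**
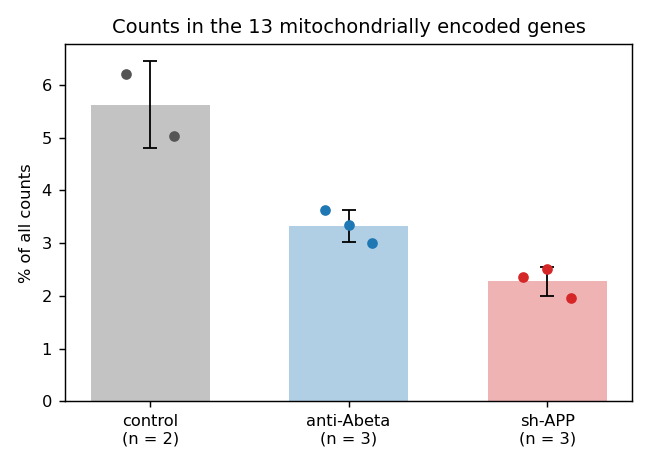
Share of all counts in the 13 mitochondrially encoded genes with a gene name (vertical axis, percent) for each library (points), with the group mean (bar height) and SD (error bar). All 6 libraries of the arms lie below both control libraries.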

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

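Of the tests below, those with 1 control library for each arm, of the library numbers, of the oxidative phosphorylation and ribosomal genes, of the proliferation median expected in anti-Abeta and of the oligodendrocyte lineage median, and the setting with library totals alone, were chosen only after the result was seen. So was the test of nuclear against mitochondrially encoded genes. No group has 4 libraries, so single libraries were not tested for standing apart.

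The direct test between the arms called 3768 genes. Median log2 differences of lists that passed that test were -1.12 for proliferation, 0.30 for astrocyte markers, 0.57 for complement, 0.23 for amyloid processing, 0.10 for pan-reactive, 0.064 for the unfolded protein and integrated stress response, -0.35 for oligodendrocyte lineage markers, 0.26 for A1, 0.13 for NF-kB targets, 0.13 for NRF2 targets, 0.50 for ependymal markers and 0.12 for immediate early genes. With an estimated correlation 0 of the 12 lists passed camera (adjusted p from 0.297 to 0.502), and 3 of all 28 did at an unadjusted p under 0.05. The 6 libraries make 10 splits, too few for a share under 0.05. The real split gave 3768 genes and 12 lists, and 1 of the 10 splits, the real one, gave as many of either. The highest of the other splits gave 0 genes in edgeR (788 at an unadjusted p under 0.05, where the real split gave 5451) and 9 lists. Each of the other splits mixes libraries of both arms, so a difference between the arms widens the spread within its groups. Their counts are therefore not a chance level for the real split.

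Both arms shared 4058 genes called the same way. The shared control libraries are argued against as the whole cause: the covariance of the fold changes exceeded the mean of simulated unchanged groups by 0.247, and with a control library of its own for each arm, assumed to vary like the other groups, it was 0.259 or 0.281 (0.0221 at most in simulations). In these fits 422 or 2123 genes were called the same way and 1 or 3 in opposite ways. Preparation in the order of the library numbers cannot be told apart from the groups, since the numbers run group by group and 0 of 3 pairs of groups interleave. A bias by transcript sequence or length stays open, as members of the same complexes moved apart alike in both arms. Over 113 oxidative phosphorylation and ribosomal genes r was 0.931, and simulated unchanged groups with the shared controls gave up to 0.816. With a control library for each arm r was 0.807 or 0.738, and simulations gave up to 0.443. All these simulations drew each gene independently, while the estimated correlation within the 2 lists was 0.354 and 0.596, so their maxima may be too low. A biological effect of less amyloid beta stays open beside the bias.

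Mitochondrially encoded transcripts were lower in both arms. A fall of the whole respiratory chain is argued against by its nuclear genes, whose median in sh-APP was 0.026. Their lowest member, at -0.98, lay above the highest of the 13 mitochondrial genes with a gene name, at -1.18. Handling or library preparation in the order of the library numbers may also lower the share, and 0 of 3 pairs of groups interleave, so this cannot be told apart from the groups. A biological change in mitochondria with less amyloid beta stays open and was not tested.

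Proliferation genes were lower in sh-APP and the list did not pass in anti-Abeta; with an estimated correlation it passed in neither (adjusted p = 0.609 and 0.919). A larger step along the changes shared by both arms would put the anti-Abeta median at -0.73. It was -0.069 (-0.24 to 0.03 with each library left out, and 0.08 with library totals alone). The expected median rests on the fold-change ratio of genes called the same way in both arms, a choice that favours large anti-Abeta changes. A step at the ratio of these genes is argued against as the whole cause, and a step at a lower ratio stays open. A loss of dividing oligodendrocyte-lineage cells, which the labels do not name, may contribute: the median of its 11 tested markers in sh-APP was -0.032, with Pdgfra (33.7 to 16.9 CPM) and Ugt8 (-2.37) lower and the abundant Olig1 higher (1819 to 2263 CPM), which leaves it open. Effects of the hairpin on melanoma products other than amyloid beta, or of the antibody leaving part of it, were not tested and stay open. The library names give the same hairpin in each sh-APP library. Where the antibody is named in the anti-Abeta libraries, the other libraries have the word control. Whether that stands for a control antibody or for none is not given in the sources used here. Effects of that hairpin beyond its target, or of adding an antibody as such, were not tested either.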

How the results depend on the processing

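Of the tests here, library totals alone and the fit without the 13 mitochondrial genes with a gene name were chosen after the data were seen. Named genes were run with DESeq2, its kind of size factors, the replicate block, library totals alone and each library left out. None reversed in these: of 236 named results 230 were called, and 140 kept the call in all of them. Reversed here means a change of sign in a result called in either setting. With library totals alone, without control replicate 1 and without control replicate 2, 1 uncalled result each changed sign. Under the other tools, factors, filters and spread, all counts of changed genes stayed within 1.5 times. They were 7769 with DESeq2 and 7614 with limma-voom in sh-APP, and 4646 and 4109 in anti-Abeta. With library totals alone the median log2 fold change of all genes moved to 0.23 in sh-APP, 0.18 in anti-Abeta and 0.21 in their mean, and 71.7% of anti-Abeta calls were higher instead of 43.4%. With upper-quartile factors 53.9% were. Of 112 list medians, 12 changed sign with library totals alone, and 0 of these passed in either setting. Without the 13 mitochondrial genes with a gene name 99.8% of the sh-APP calls were kept. Mitochondrial transcripts without a gene name stayed in that fit.

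Leaving out each library gave 5942 to 7954 genes in sh-APP, 439 to 4775 in anti-Abeta, 2233 to 3582 between the arms, 4490 to 7316 for the mean of both arms, 435 to 4558 shared by both arms, and a correlation of 0.656 to 0.808. A fit with 1 control library assumes that it varies like the other groups, and it has fewer samples. The stricter filter gave a correlation of 0.850, on fewer genes. Lists passing ran from 1 to 3 in anti-Abeta and 3 to 5 for the mean of both arms. With camera's estimated correlation 0 lists passed in each of the 4 contrasts (1, 1, 3 and 1 at an unadjusted p under 0.05 in sh-APP, anti-Abeta, between the arms and the mean). With fry, which does not compare a list with other genes, 16 passed in sh-APP, 3 in anti-Abeta, 16 between the arms and 15 for the mean. For the other changes the cause was not tested. Whether replicate numbers pair the libraries is not settled, as deviations of the same number correlated from -0.0106 to 0.105. Between sh-APP and anti-Abeta, replicates 1 and 2 gave 0.105 and 0.0984 for the same number, and -0.101 and -0.108 for different numbers. Replicate 3 gave -0.0056. With the number as a block, 7328, 3480, 3675 and 6558 genes changed in sh-APP, anti-Abeta, between the arms and in the mean, and 2 lists passed for the mean. Of the named results 8 lost the call in edgeR's test with this block. Among them were Clu in anti-Abeta (adjusted p = 0.0675), and Rsph1 (0.0559), Tekt1 (0.100) and Dnah12 (0.0723) in sh-APP. A fit of only the groups compared has no value for the mean of both arms. In simulated data the depth and spread recovered 47.8% of 1.5-fold changes in sh-APP, so small changes can be missed. Only 200 of 14196 genes were changed there, against 7750 called in sh-APP. The recovered share may differ in the real data, and TMM scaling under so many changes was not checked.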

Other observations

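These gene groups were fixed in advance, and the correlations between arms were computed after the data were seen. Members of the same machinery moved apart in sh-APP. Of 45 tested nuclear genes of oxidative phosphorylation, 19 rose and 16 fell. Atp5d of ATP synthase rose by 0.81 ± 0.09 on the log2 scale (SE), and Ndufs7 and Ndufs8 of complex I rose by 0.71 ± 0.09 and 0.63 ± 0.08, while Ndufs1 of the same complex had -0.52 ± 0.07. Of 68 cytosolic ribosomal protein genes, 27 rose and 13 fell, with Rpsa at 0.58, Rpl13 at 0.63 and Rpl30 at -1.34. Ribosomal protein genes have many near-identical copies in the genome, and how reads that match several of them were counted is not given in the sources used here. Neither list passed (camera adjusted p = 0.764 and 0.0904). In anti-Abeta 10 rose and 16 fell in the first (14 and 16 adjusted over the list alone) and 17 rose and 8 fell in the second (19 and 8), and the fold changes of the arms correlated across genes at 0.984 and 0.907. Simulated unchanged groups with the same shared controls gave up to 0.784 and 0.871. These simulations drew each gene independently and the real genes are not independent, so the maxima may be too low.

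Cholesterol synthesis, glycolysis and protein folding genes also moved both ways in sh-APP. Of 25 cholesterol synthesis genes, 11 rose and 10 fell, with Mvk, an early kinase of the pathway, at 0.75 and Idi1, Hsd17b7 and Msmo1 at -1.36, -1.14 and -0.74. Of 31 hypoxia and glycolysis genes, 12 rose and 7 fell (9 and 5 in anti-Abeta). The glycolytic enzymes Gapdh, Eno1 and Aldoa rose by 0.68 ± 0.07, 0.65 ± 0.08 and 0.61 ± 0.07, and Bnip3, a mitochondrial protein induced by hypoxia, had -0.81 ± 0.09. The same holds for near-identical copies of Gapdh, Eno1 and Aldoa. Of 32 genes of the unfolded protein and integrated stress response, 12 rose and 5 fell (8 and 4 in anti-Abeta), with Phgdh of serine synthesis at 0.75 and the chaperones Dnajb9 and Hsp90b1 at -1.65 and -0.62. Of 14 heat shock genes, 6 rose and 4 fell (2 and 4 in anti-Abeta), with Hspb1 up and Dnaja1, Hspd1 and Chordc1 at -0.88, -0.92 and -1.29. Of 23 NRF2 targets, 11 rose and 6 fell, with Nqo1, a quinone reductase, at 0.95 and Prdx1 at -0.79. None of these 5 lists passed in sh-APP (adjusted p from 0.265 to 0.804).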
